A study of Homo sapiens with 36 samples.

How the data were processed

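RNA was measured by sequencing in 36 libraries of 6 Ewing sarcoma cell lines, each exposed to DMSO or to SP-2509 at 2 uM for 48 h, with 3 replicates in each of 12 groups. Per the labels' protocols, cells were seeded at 20 to 25 percent confluency, RNA was isolated on RNeasy columns with DNase treatment, and 2.5 ug of total RNA entered an Illumina ScriptSeq preparation. Per the submitters' processing notes, bcl2fastq, STAR 2.5.1b, HTSeq and DESeq2 were used with the genome build GRCh38.p6. The gene annotation, the counting options and the use of strand were not given in the sources used here.

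The authors deposited a single table of regularised log2 values from DESeq2, per the file headers and the submitters' processing notes, with 1 column for each of the 36 libraries. A regularised log value is a log2 expression level adjusted for library size, and its differences are shrunk towards 0 for genes with few reads. Whether the transformation was told the groups was not given in the sources used here. The table held 44095 entries, of which 38861 varied between libraries and 5234 were at exactly 0 in every library. No read counts were used here, so the depth of each library is unknown, no count test was run, and the precision of a value comes only from the spread between replicates.

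Samples were grouped by the cell line, the treatment and the sensitivity class in the labels. Genes with a mean value of at least 3 over the 36 libraries were tested, which left 15564, and 12429 reached a mean of 5. Of the tested genes, 14681 had a name in the reference tables and 13577 matched GENCODE 29 by name. Coordinates are those of GENCODE 29 on GRCh38. Column names matched the library titles, and 0 columns were left unmapped.

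Within each line, SP-2509 was compared with DMSO in limma 3.58.1 under R 4.3.3, in a single fit of all 36 libraries with a treatment term per line and a block for each of the 18 pairs of line and replicate number. The pairing rests on the series' design text, which describes paired RNA from 3 experiments per line. It was checked from the values. Deviations from the group means correlated by 0.0601 on average between libraries of the same number (lowest -0.00161, highest 0.187) and by -0.0299 between other numbers. Deviations within a group sum to 0, so the second mean largely follows from the first and is no separate check. Of the 18 pairs, 5 exceeded 0.1. Of the DMSO libraries, 11 lay closest to their own number, with 3 candidates each. For statements over lines, the 3 paired differences of a line were averaged, so that the cell line is the replicate. The mean response tested 6 such values against 0, and the class comparisons tested 3 hypersensitive against 3 sensitive lines, for the response and for the DMSO level. Those tests take the lines of a class as independent. TC32 and TC252, both hypersensitive, were the most alike pair under DMSO, with an SD over genes of their difference of 0.440. The class p-values from limma may therefore overstate the evidence. P-values were moderated by limma with a trend in the prior spread and adjusted by the method of Benjamini and Hochberg, with 0.05 as the threshold. Every adjusted p in the text is from limma or from limma's camera unless another test is named.

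The trend can be placed on a gene's mean expression or on the mean of the tested values, and the fixed wording of the test allows both readings. An early fit had the trend on the tested values, which called no gene in the class comparison of responses. It was replaced by the trend on mean expression, then restored, and replaced again after it was seen to leave CREBRF, DNAJB9 and DDIT3 uncalled in the mean response. The trend on mean expression was thus adopted only after both fits had been seen, so the choice is not independent of the outcome. The results under both readings are given beside the comparisons that they change.

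Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 25 lists that had at least 5 measured members. There were 29 lists: PERK-ATF4 targets, ATF6-XBP1 chaperones and ERAD, apoptosis of the ER stress and BH3 kind, genes activated and genes repressed by EWSR1-FLI1, LSD1-CoREST and NuRD complexes, G2 and mitosis, S phase and replication, p53 targets, NRF2 and oxidative stress, heat shock, metallothioneins and zinc, hypoxia and iron, cholesterol synthesis, glycolysis, oxidative phosphorylation of the mitochondrial and of the nuclear genome, cytosolic ribosomal proteins, interferon response, NF-kB and cytokines, immediate early genes, autophagy and lysosome, neuronal differentiation, mesenchymal and matrix genes, histone genes dependent on replication, and epithelial, haematopoietic, skeletal muscle and endothelial markers. No list call in any of the 3 comparisons held with an estimated correlation.

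The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, with the series title known, which names the ER-stress response. For the mean response, the rule took the 12 called genes with the largest increase and the 12 with the largest decrease among genes with an official symbol (names beginning with LOC left out), a mean of at least 5 and the same direction in all 6 lines. For each class comparison it took up to 10 called genes per direction with a mean of at least 5, or, where fewer than 5 genes were called, the 5 with the smallest unadjusted p per direction. For each line it took 3 called genes per direction with a symbol and a mean of at least 5, and for each list the 2 members with the largest and the 2 with the smallest mean response. KDM1A was named in any case, and genes of the Y chromosome and XIST were never named. Genes outside the rule are marked as chosen after their values were seen.

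The tests were run on simulated data with 76, 66 and 58 genes changed by a log2 of 0.5, 1 and 2 among 15564. For 1 line with 3 pairs, 65.8 percent of genes changed by a log2 of 0.5 were recovered, 95.5 percent at 1 and 100 percent at 2, with 9 false calls. For the mean response over 6 lines the shares were 28.9, 84.8 and 98.3 percent, with 8 false calls. For the class difference in response they were 0, 12.1 and 69.0 percent, with 0 false calls, and for the class difference under DMSO 0, 7.58 and 41.4 percent, with 3 false calls. With the trend on the tested values, the mean response recovered 19.7, 81.8 and 96.6 percent and the class difference in response 0, 9.09 and 74.1 percent. Both forms of camera recovered 3 of 3 shifted lists, and 1 of 27 unshifted lists was called with the preset correlation against 0 with the estimated one. Genes were simulated independently, so these lists held no correlation between genes. The simulation therefore cannot show how often the preset correlation gives false calls for correlated lists. In the data, the estimated correlation in the mean response was highest for the G2 and mitosis list, at 0.82. For hypoxia and iron it was -0.01, below the preset value, yet that list also lost its call (adjusted p 0.0179 and 0.405, camera). A high correlation within a list is therefore not the only reason for a lost call. What else removed these calls was not tested.

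Alternatives were the filter on low values, centring each library on its median, quantile normalisation, the trend, a minimum log2 difference of 1, fits without the replicate block, fits on the spread between pairs or libraries, and leaving out each replicate or line. Fits without TC252 replicate 3, without TC32 replicate 2 and with the trend on the tested values were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.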

Results

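Transcript levels were measured in 6 Ewing sarcoma cell lines, tumour lines that carry a fusion of EWSR1 with an ETS gene, after 48 h with 2 uM SP-2509, a reversible inhibitor of the histone demethylase LSD1 (gene KDM1A), or with the vehicle DMSO. A673, TC32 and TC252 are hypersensitive to the compound, with an IC50 below 300 nM, and EWS-502, ES-2 and TC71 are sensitive, with an IC50 above 900 nM. Each of the 12 groups held 3 libraries, 36 in all, from 3 paired experiments per line. The values are regularised log2 levels, so the depth of each library is unknown. Between 15174 and 15765 entries per library reached a value of 3, and the median over tested genes lay between 8.39 and 8.67. Root mean square differences between the DMSO libraries of a group ran from 0.204 to 0.298. Among SP-2509 libraries they reached 0.489 in TC32 and 0.662 in TC252, where replicate 3 stood apart.

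The first comparison asked which transcripts SP-2509 changed across the 6 lines. CREBRF, a regulator of the unfolded protein response, rose by a mean log2 of 2.98 ± 0.50 (SD, n = 6 lines), DNAJB9, a co-chaperone of the endoplasmic reticulum (ER), by 2.61 ± 0.79, and DDIT3, which encodes the stress transcription factor CHOP, by 2.48 ± 0.66. PPP1R15A, whose product directs dephosphorylation of eIF2 alpha, rose by 2.18 ± 0.46, and WIPI1, an autophagy gene, by 2.17 ± 0.74. SAT1, the catabolic enzyme of polyamines, rose by 2.07 ± 0.84, ULBP2, a ligand of the receptor NKG2D, by 1.98 ± 0.91, and OSGIN1 by 1.96 ± 0.68. ESRP1, an epithelial splicing regulator (2.22 ± 1.11), the matrix protein gene CYR61 (2.13 ± 1.02), LAMP3 (1.97 ± 1.29) and ARAP2 (1.96 ± 1.00) also rose, with wide differences between lines. Among genes with a mean of at least 5 and the same direction in all 6 lines, to which these examples are limited, the largest decreases were those of the transfer RNA gene TRT-TGT6-1, which fell by 2.50 ± 0.99, the histone gene HIST1H3J, by 2.47 ± 0.50, APELA, a peptide ligand gene, by 2.36 ± 0.90, and LPAR4, a lysophosphatidic acid receptor gene, by 2.13 ± 0.70. HIST1H3A (-2.09), KCNE3 (-1.95), FAM111B (-1.94), the long noncoding RNA EWSAT1 (-1.91) and 4 further transfer RNA genes, TRV-AAC3-1 (-2.07), TRT-TGT4-1 (-1.97), TRI-AAT5-3 (-1.92) and TRQ-CTG6-1 (-1.83), completed the 12 decreases. Copies of transfer RNA and histone genes share reads, so values of single copies are uncertain. Whether reads assigned to transfer RNA genes came from mature transfer RNA, precursors or overlapping transcripts was not examined.

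Of 15564 genes tested, 7111 passed the test of the mean response in limma, 3327 higher and 3784 lower, and 853 of them changed by a log2 of at least 1 (332 higher, 521 lower). The balance of directions depended on scaling, with 3845 higher and 3191 lower after each library was centred on its median and 3618 and 3575 after quantile normalisation. Adjusted p was 1.6e-05 for CREBRF, 0.000162 for DNAJB9, 0.000126 for DDIT3, 6.6e-05 for HIST1H3J and 0.000251 for APELA. With the trend of the prior spread on the tested values, 7358 genes passed, but CREBRF (adjusted p = 0.341), DNAJB9 (0.121) and DDIT3 (0.0741) did not. On GRCh38 (GENCODE 29), CREBRF lies on chromosome 5 from 173056352 to 173139284, DNAJB9 on chromosome 7 from 108569568 to 108574850, DDIT3 on chromosome 12 from 57516588 to 57521737, HIST1H3J on chromosome 6 from 27890382 to 27893106 and APELA on chromosome 4 from 164877004 to 164898965. ESRP1 lies on chromosome 8 from 94641074 to 94707466, PPP1R15A on chromosome 19 from 48872392 to 48876057 and EWSAT1 on chromosome 15 from 69072926 to 69095820.

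**Figure D1:**
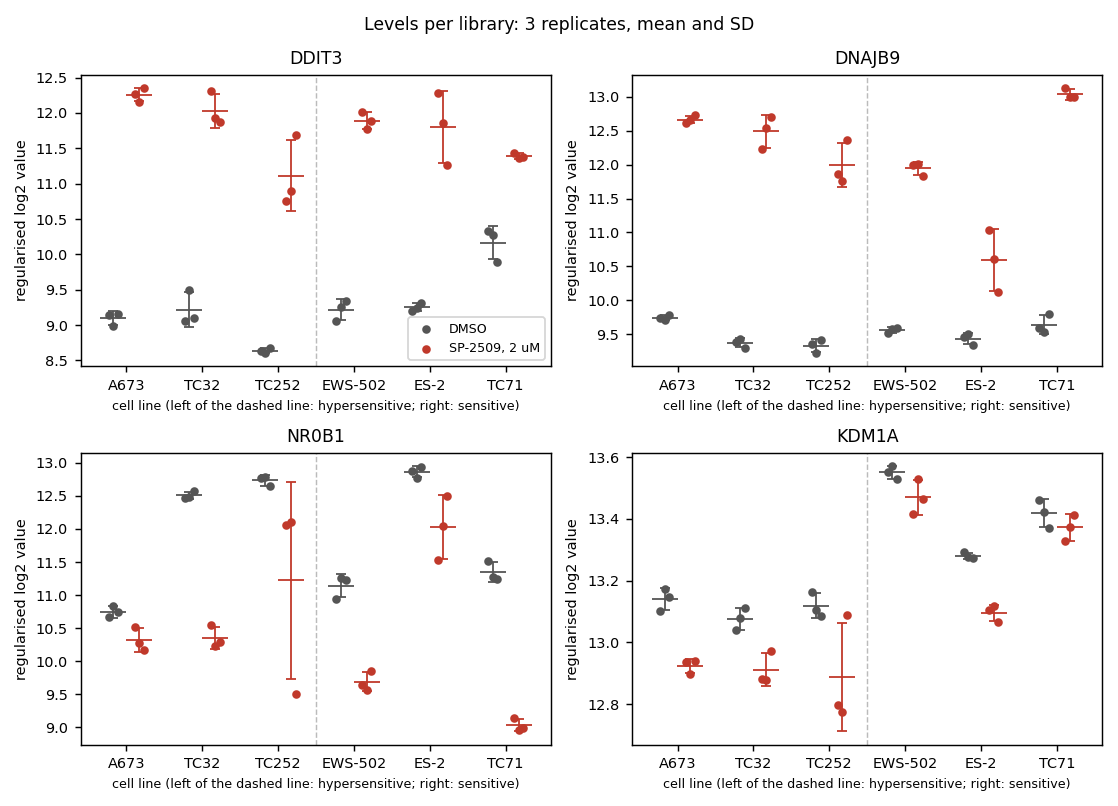
Regularised log2 level of DDIT3, DNAJB9, NR0B1 and KDM1A in each of 36 libraries, by cell line, with DMSO in grey and SP-2509 in red. Points are the 3 replicates, lines the mean with its SD, and the dashed line parts hypersensitive from sensitive lines. DDIT3 and DNAJB9 were higher with SP-2509 in every line, by 1.23 to 3.16 and by 1.16 to 3.40.

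Genes of the ER stress response rose together. In the list of ATF6 and XBP1 chaperones and degradation factors, 28 of 29 measured members rose, 0 fell and 1 was not called, with a median log2 of 0.74; adjusted over the list alone, 29 rose. DNAJB9 rose by 2.61 ± 0.79, the stress sensor ERN1 by 1.74 ± 0.56, the chaperone HSPA5 (BiP) by 1.69 ± 0.70 and the transcription factor XBP1 by 1.62 ± 0.47, while CRELD2 rose by 0.38 ± 0.43 and DNAJB11 stood at 0.31 ± 0.37 without passing. In the list of PERK and ATF4 targets, 21 of 31 rose, 0 fell and 10 were not called, with a median of 0.69; adjusted over the list alone, 22 rose. Its largest increases were those of DDIT3, at 2.48, and of the cytokine gene GDF15, at 2.32 ± 1.29. ATF4 itself rose by 0.88 ± 0.18, and SLC7A5, an amino acid transporter gene, stood at -0.28 ± 0.48 and CEBPB at -0.13 ± 0.22 without passing. By camera with the preset correlation, adjusted p was 4.0e-11 for the first list and 2.3e-07 for the second, and it was 0.502 for each with an estimated correlation. The series title names this response, so the choice of both lists was not independent of the study. By line, the median of the chaperone list ran from 0.14 in ES-2, with 11 members higher and 0 lower, to 1.26 in TC71, with 29 higher, and that of the PERK and ATF4 list from 0.14 in TC71, with 15 higher and 9 lower, to 1.48 in A673, with 30 higher. HSPA5, XBP1 and ATF4 lie outside the naming rule and were chosen after their values were seen.

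Genes known to be activated by the EWSR1-FLI1 fusion protein fell. Of 35 measured members, 24 fell, 0 rose and 11 were not called, with a median of -0.71; adjusted over the list alone, 26 fell. NR0B1, a nuclear receptor gene bound by the fusion, fell by 1.45 ± 0.73 and UGT3A2 by 1.33 ± 0.31, while GLI1 (-0.00 ± 0.24) and JAK1 (-0.00 ± 0.25) did not pass. The cell cycle gene CCND1 (-1.32 ± 0.57) and the transcription factor gene NKX2-2 (-0.80 ± 0.32), chosen after their values were seen, also fell. NR0B1 was not called in A673, at -0.43 (SE 0.29, adjusted p = 0.229), and fell most in TC71, by 2.31. It lies on the X chromosome from 30304206 to 30309598. In TC252 it fell by 1.51, with an SD of 1.41 between the 3 pairs, where SP-2509 replicate 3 lay at 9.50 and replicates 1 and 2 at 12.06 and 12.11. Camera gave the list an adjusted p of 1.3e-08, and 0.405 with an estimated correlation. Of 29 measured genes known to be repressed by the fusion, 11 rose, 5 fell and 13 were not called, both over all genes and adjusted over the list alone. The matrix genes CYR61 (2.13 ± 1.02) and CTGF (1.54 ± 0.91) rose, and COL1A1, a collagen gene, fell by 0.94 ± 0.51 and TIMP3, a protease inhibitor gene, by 0.89 ± 0.87. That list had a median of 0.39 and an adjusted p of 0.0181, which was 0.502 with an estimated correlation. Without the line A673, the gene list EWSR1-FLI1 repressed genes did not pass (adjusted p = 0.0583).

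Genes of DNA replication and histone genes fell. In the S phase list, 22 of 25 members fell, 0 rose and 3 were not called, with a median of -0.91; adjusted over the list alone, 23 fell. The cyclin gene CCNE2 fell by 1.78 ± 0.98 and GINS2, of the replicative helicase, by 1.49 ± 0.49, while the licensing factor genes CDT1 (-0.21 ± 0.60) and CDC6 (-0.19 ± 0.53) did not pass. Adjusted p was 1.2e-09, and 0.502 with an estimated correlation. Of 16 histone genes, 15 fell and 1 was not called, with a median of -0.95; adjusted over the list alone, 15 fell and 1 rose. The linker histone gene HIST1H1B fell by 1.52 ± 1.02, HIST1H2BG by 1.39 ± 0.84 and HIST2H2BE by 0.37 ± 0.33. H1F0, at 0.28 ± 0.37, encodes a linker histone that is not tied to replication. Camera gave the histone list an adjusted p of 6.8e-06, and 0.502 with an estimated correlation. In the list of G2 and mitosis, 10 of 25 fell, 0 rose and 15 were not called, with a median of -0.31; adjusted over the list alone, 9 fell. HMMR (-1.12 ± 0.52) and the kinase gene AURKB (-0.75 ± 0.42) fell, and UBE2C (0.19 ± 0.60) and TTK (0.18 ± 0.35) did not pass. Its adjusted p was 0.00873, and 0.637 with an estimated correlation.

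**Figure D2:**
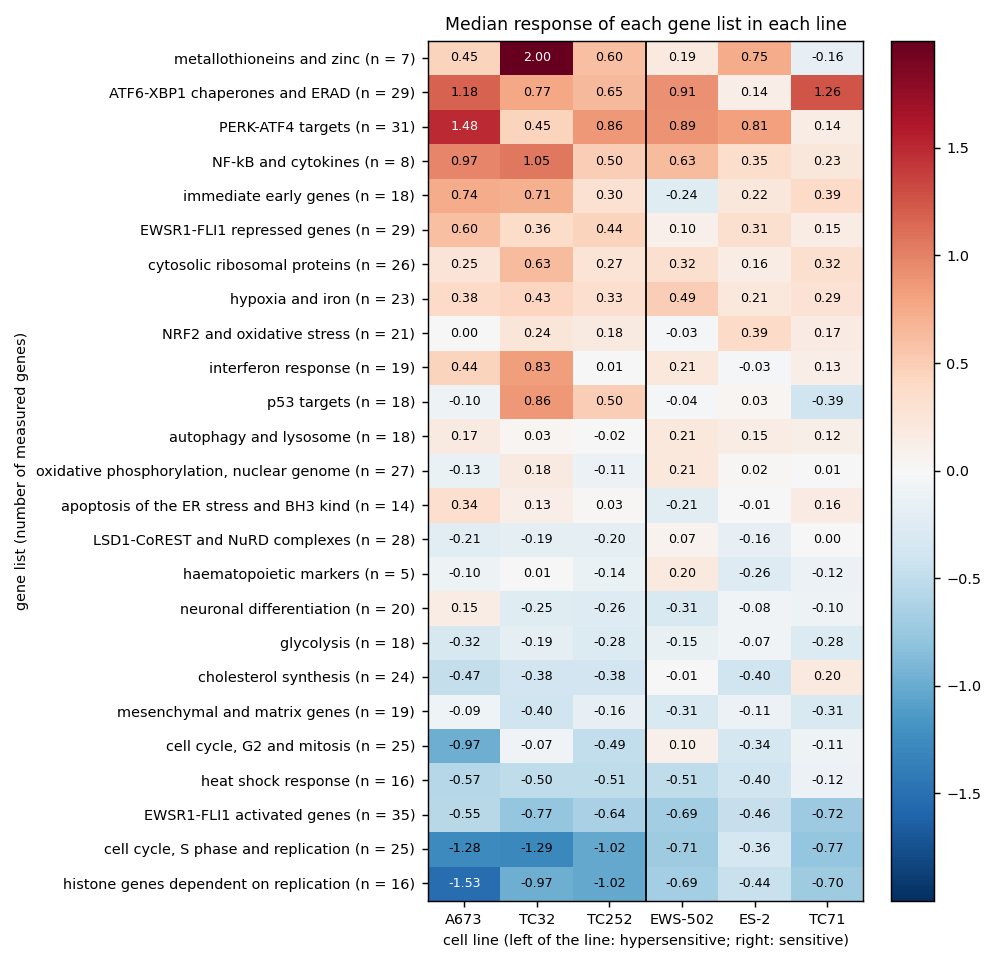
Median log2 difference of SP-2509 against DMSO over the measured members of 25 gene lists (vertical axis) in 6 cell lines (horizontal axis), as a colour scale. The S phase list lay below 0 in every line, from -1.29 in TC32 to -0.36 in ES-2, and the list of ATF6 and XBP1 chaperones above 0 in every line.

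Of 26 cytosolic ribosomal protein genes, 24 rose, 0 fell and 2 were not called, with a median of 0.34 and the same counts adjusted over the list alone. RPL11 rose by 0.46 ± 0.21 and RPL30 by 0.45 ± 0.26, and RPL8 (0.15 ± 0.13) and RPS18 (-0.03 ± 0.25) did not pass. Adjusted p was 1.2e-06, and 0.502 with an estimated correlation. In the heat shock list, cytosolic chaperones for the most part, 13 of 16 fell, 1 rose and 2 were not called, with a median of -0.45 and the same counts adjusted over the list alone. HSPB1 fell by 0.94 ± 0.27 and DNAJA1 by 0.79 ± 0.36, CRYAB rose by 0.64 ± 0.63, and BAG3 stood at 0.29 ± 0.46. Camera gave 0.00143, and 0.502 with an estimated correlation, both adjusted p. Of 8 NF-kB and cytokine genes, 6 rose, 0 fell and 2 were not called, and 7 rose adjusted over the list alone. The adhesion molecule gene ICAM1 rose by 1.17 ± 0.79 and RELB by 1.09 ± 0.40, and NFKB1 (0.21 ± 0.23) and NFKBIA (0.45 ± 0.58) did not pass. The median was 0.63 and the adjusted p 0.00162, and adjusted p = 0.470 with an estimated correlation.

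In the list of hypoxia and iron genes, 12 of 23 rose, 5 fell and 6 were not called, with the same counts adjusted over the list alone and a median of 0.29. NDRG1 rose by 1.95 ± 0.59 and the glucose transporter gene SLC2A3 by 1.87 ± 0.71. The 5 that fell were ANGPTL4 (-0.81 ± 0.77), EGLN3 (-0.68 ± 0.52) and the glycolytic genes PGK1 (-0.47), LDHA (-0.40) and ENO1 (-0.34), which the glycolysis list also holds and which were chosen after their values were seen. Adjusted p was 0.0179, and 0.405 with an estimated correlation. Of 18 immediate early genes, 9 rose, 1 fell and 8 were not called, with the same counts adjusted over the list alone and a median of 0.46. The transcription factor genes KLF4 (1.69 ± 1.04) and NR4A1 (1.17 ± 0.36) rose, EGR2 fell by 1.04 ± 1.01, and MYC stood at -0.30 ± 0.44. Its adjusted p was 0.0147, and 0.546 with an estimated correlation. Of 7 metallothionein and zinc genes, 5 rose, 0 fell and 2 were not called, with the same counts adjusted over the list alone and a median of 0.76. MT1X (0.99 ± 0.96) and MT1E (0.92 ± 0.91) rose, and MT1F (0.58 ± 1.02) and SLC39A10 (-0.23 ± 0.30) did not pass. The adjusted p of 0.0430 was 0.502 with an estimated correlation, and the list no longer passed without TC252 replicate 3, when 13 lists did. In the cholesterol synthesis list, 9 of 24 fell, 1 rose and 14 were not called, with the same counts adjusted over the list alone and a median of -0.20. FDPS, an enzyme gene of the pathway, fell by 0.90 ± 0.24, SC5D rose by 0.23 ± 0.16, and the regulator gene SREBF2 stood at 0.28 ± 0.34. Adjusted p was 0.0213, and 0.560 with an estimated correlation. In all, 14 of 25 lists passed with the preset correlation, and 9 did so without the line A673.

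The other 11 lists did not pass. In the list of ER stress and BH3 apoptosis genes, 4 of 14 rose, 2 fell and 8 were not called, with the same counts adjusted over the list alone and an adjusted p of 0.515. Its median was -0.02, its mean 0.11 and its test direction upward, so these differ in sign. BBC3 (1.10 ± 0.78) and HRK (1.09 ± 1.20) rose, and BID (-0.76 ± 0.31) and BMF (-0.49 ± 0.53) fell. Among 18 p53 targets, 4 rose, 3 fell and 11 were not called (4 and 2 adjusted over the list alone, adjusted p = 0.254). GADD45A (1.52 ± 0.68) and PLK3 (1.10 ± 0.43) rose, and TP53I3 (-0.90 ± 0.33) and BTG2 (-0.58 ± 0.34) fell. Of 21 NRF2 genes, 6 rose, among them OSGIN1 (1.96) and FTL (1.06 ± 0.39), and 1 fell, TXN (-0.28 ± 0.16), with the same counts adjusted over the list alone and adjusted p = 0.0731. Of 18 autophagy and lysosome genes, 4 rose and 0 fell, with the same counts adjusted over the list alone (WIPI1 at 2.17, GABARAPL1 at 0.66 ± 0.15, adjusted p = 0.0706). Of 19 interferon genes, 5 rose and 1 fell (5 and 0 adjusted over the list alone), with IRF9 at 0.88 ± 0.66 and OAS3 at -0.44 ± 0.39 (adjusted p = 0.0873). Of 18 glycolysis genes, 2 rose and 7 fell, with the same counts adjusted over the list alone, TPI1 at -0.78 ± 0.29 and ALDOC at 0.61 ± 0.52 (adjusted p = 0.166). Of 19 mesenchymal and matrix genes, 2 rose and 8 fell, also when adjusted over the list alone, with PDGFRB at -1.23 ± 0.61 and ZEB1 at 0.81 ± 0.35 (adjusted p = 0.188). Of 20 neuronal genes, 2 rose and 3 fell, also when adjusted over the list alone, with NEFH at -0.84 ± 0.67 and SYP at 0.58 ± 0.32 (adjusted p = 0.537). Of 27 nuclear genes of oxidative phosphorylation, 3 rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.485), with UQCRC2 at 0.42 ± 0.18. Of 5 haematopoietic markers, only CORO1A fell, at -0.89 ± 0.56 (1 adjusted over the list alone, list adjusted p = 0.857). The lists of epithelial (4 measured), skeletal muscle (4) and endothelial markers (2) and of the mitochondrial genome (0 of 13) were too small to test.

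KDM1A, the target of the compound, stood at a mean response of -0.15 ± 0.07, which did not pass over the 6 lines (adjusted p = 0.0802). Within lines it fell by 0.22 in A673, 0.16 in TC32, 0.23 in TC252 and 0.18 in ES-2 (SE 0.07 each), and was not called in EWS-502 (-0.08, adjusted p = 0.305) or TC71 (-0.05, adjusted p = 0.550). After quantile normalisation the mean response passed, at -0.21. Of 28 measured members of the LSD1-CoREST and NuRD complexes, 5 rose, 8 fell and 15 were not called, with the same counts adjusted over the list alone. RCOR3 (0.98 ± 0.46) and KDM1B (0.78 ± 0.32), the paralog of KDM1A, rose, while the remodeller CHD4 fell by 0.81 ± 0.14 and RBBP4 by 0.65 ± 0.18. As a list the complexes did not pass (adjusted p = 0.515). KDM1A lies on chromosome 1 from 23019443 to 23083689. An inhibitor need not change the RNA of its target, so KDM1A is no check of the labels.

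The genes named by line are the extremes among those with an official symbol (names beginning with LOC left out) and a mean level of at least 5, so lower genes such as GDF15, at 3.18 in TC252, can exceed them. Within A673, the largest such changes were increases of PTX3, a secreted pentraxin, by 5.51 (SD 0.24 over 3 pairs), of ANKRD1 by 4.94 (SD 0.58) and of LAMP3 by 4.22 (SD 0.04), and decreases of the histone genes HIST1H2BM (-3.94), HIST1H2AJ (-3.38) and HIST1H2BB (-3.27). In TC32, CREBRF (3.48), CYR61 (3.32) and DNAJB9 (3.12) rose most, and NEUROD6, a neurogenic transcription factor gene, fell by 3.54, TRT-TGT6-1 by 3.48 and HIST1H2AH by 3.12. In TC252, CREBRF (2.74, SD 1.21), DNAJB9 (2.66, SD 0.25) and DDIT3 (2.47, SD 0.47) rose most, and HIST1H2BM (-2.46), HIST1H3J (-2.32) and HIST1H2AH (-2.23) fell most. EWS-502 had CREBRF (3.50), ESRP1 (3.50) and ASB11 (3.02) as its largest increases and NWD1 (-3.14), LINC00925 (-2.94) and BEND3 (-2.93) as its largest decreases. For ES-2 these were ESRP1 (2.90), CREBRF (2.73, SD 0.74) and DDIT3 (2.55, SD 0.57), and MROH2A (-1.89), APELA (-1.66) and HIST1H3J (-1.63). In TC71, DNAJB9 (3.40), ULBP2 (3.22) and CREBRF (3.18) rose most, and APELA fell by 4.16, TRN-GTT6-1 by 4.05 and TRY-GTA5-3 by 3.74.

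The number of genes called within a line in limma was 8379 in A673 (4181 higher, 4198 lower), 10127 in TC32 (4833, 5294), 7348 in TC252 (3405, 3943), 9225 in EWS-502 (4415, 4810), 3823 in ES-2 (1771, 2052) and 10325 in TC71 (4943, 5382). With the spread of the line's own libraries alone, the treatment response in TC252 had 965 calls. The treatment response in ES-2 had 939 calls without replicate 1 and 1915 without replicate 2. In TC71, 47.9 percent of calls were higher, and 61.1 percent after each library was centred on its median, a centring that moved the line's median response from -0.02 to 0.16. The majority of calls also turned from lower to higher with centring in TC32 (52.4 percent higher), TC252 (53.6 percent) and EWS-502 (54.2 percent), and from lower to higher by a small margin in A673 (50.3 percent). In ES-2 the higher share moved the other way, from 46.3 to 39.7 percent. In all 6 lines, 710 genes rose and 818 fell, where 2.91 and 5.10 would do so if the lines were independent. In the 3 hypersensitive lines these were 1975 and 2216 genes (284 and 362 if independent), and in the 3 sensitive lines 989 and 1165 (160 and 219). Counted over all genes, and so overlapping with these, 2447 were called in opposite directions in at least 1 pair of lines.

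The next comparison asked whether hypersensitive lines responded differently from sensitive lines. HIF1A-AS2, a long noncoding RNA, rose by 2.41 in A673, 2.94 in TC32 and 2.27 in TC252, against 0.23 in EWS-502, 0.14 in ES-2 and 0.17 in TC71, a class difference of 2.36 (SE 0.28, adjusted p = 0.0382, n = 3 lines per class, limma). LOC105370526 differed by 4.05 (SE 0.30, adjusted p = 0.00153), with 4.71, 4.53 and 4.18 against 0.55, 0.15 and 0.57. It has a mean of 4.51, below the naming rule, was chosen after its values were seen, and was not placed by the reference tables. The histone gene HIST1H2AJ differed by -2.72 (SE 0.32, adjusted p = 0.0382), with -3.38, -2.85 and -2.05 against -0.32, 0.22 and -0.02. In the sensitive lines it lay near 7.4 under DMSO, against 12.7 in the hypersensitive lines, and those DMSO libraries enter both values. HIF1A-AS2 lies on chromosome 14 from 61715558 to 61751097 on the minus strand (GRCh38, GENCODE 29), overlapping HIF1A, which runs from 61695513 to 61748259 on the plus strand. The use of strand in counting was not given, so the sources do not show whether reads of the overlapping pair were kept apart, and HIF1A itself had a class difference in response of -0.02 (SE 0.27). HIST1H2AJ lies on chromosome 6 from 27814354 to 27814740.

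These were the only 3 genes called of 15564, and the choice of trend decided them. With the trend on the tested values limma called 0 genes (smallest adjusted p 1.00, 627 genes at an unadjusted p under 0.05), against 3 with the trend on mean expression (606 such genes, 778.2 expected by chance). HIF1A-AS2 did not pass after quantile normalisation (class difference in response of HIF1A-AS2 2.28, adjusted p = 0.0912, over all alternatives 0.0347 to 1.00), without replicate 3 or without any 1 of the 6 lines, and HIST1H2AJ did not pass without replicate 2 or without any 1 line except TC252. The titles number the libraries of A673, TC252 and ES-2 from 3 to 22 and those of TC32, EWS-502 and TC71 from 47 to 80. Each such block holds both classes but only 3 lines, and the line values above keep their order within each block. Not passing, with the next smallest p, were CRIM1 (1.27, adjusted p = 0.378), SNAPC1 (1.81, 0.661), TRNP1 (1.23, 0.936) and PHLDA1 (1.78, 0.999), and with negative differences HIST1H2BM (-2.72, 0.293), HIST1H2BB (-1.81, 0.970), MCM7 (-0.71, 0.999) and MCM4 (-0.73, 0.999). SNAPC1, a neighbour of HIF1A-AS2, lies on chromosome 14 from 61762357 to 61796428, and in TC252 its SP-2509 level was 14.39 in replicate 3 against 12.37 and 12.31.

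**Figure D3:**
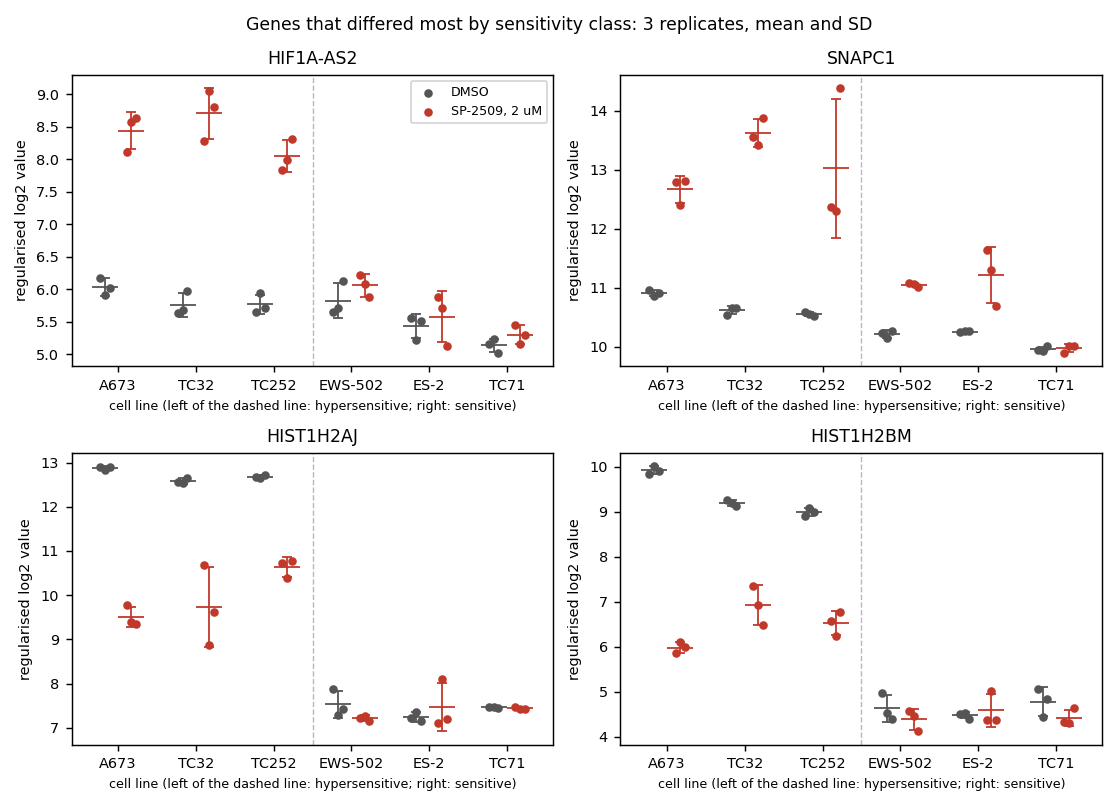
Regularised log2 level of HIF1A-AS2, SNAPC1, HIST1H2AJ and HIST1H2BM in each of 36 libraries by cell line, with DMSO in grey and SP-2509 in red, 3 replicates as points, the mean with its SD, and a dashed line between hypersensitive and sensitive lines. HIF1A-AS2 was higher with SP-2509 by 2.27 to 2.94 in the hypersensitive lines and by 0.14 to 0.23 in the others.

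No member of any list passed the class comparison of responses over all genes. As groups, 8 lists lay higher in the hypersensitive lines with the preset correlation, with median class differences of 0.41 for PERK and ATF4 targets, 0.50 for p53 targets, 0.29 for apoptosis genes, 0.32 for genes repressed by EWSR1-FLI1, 0.73 for metallothioneins, 0.46 for immediate early genes, 0.28 for NF-kB genes and 0.21 for interferon genes. A further 6 lay lower: S phase (-0.45), G2 and mitosis (-0.37), histones (-0.49), cholesterol synthesis (-0.33), heat shock (-0.16) and nuclear oxidative phosphorylation (-0.10). With an estimated correlation 0 of the 14 passed, with adjusted p of 0.278 to 0.735. Adjusted over the list alone, 2 S phase genes and 1 cholesterol gene were lower, 2 hypoxia genes, 1 apoptosis gene and 1 gene repressed by EWSR1-FLI1 were higher, 1 glycolysis gene was higher and 1 lower, and no member of the other lists passed. The p53 targets had medians of -0.10 in A673, 0.86 in TC32 and 0.50 in TC252, against -0.04, 0.03 and -0.39 in EWS-502, ES-2 and TC71. In the same order of lines, the medians of PERK and ATF4 targets were 1.48, 0.45 and 0.86 against 0.89, 0.81 and 0.14, and those of G2 and mitosis -0.97, -0.07 and -0.49 against 0.10, -0.34 and -0.11. In none of these 3 lists did the line medians part by class. Of the 14 lists, they did so for S phase (-1.28, -1.29 and -1.02 against -0.71, -0.36 and -0.77), histones (-1.53, -0.97 and -1.02 against -0.69, -0.44 and -0.70) and genes repressed by EWSR1-FLI1 (0.60, 0.36 and 0.44 against 0.10, 0.31 and 0.15). After quantile normalisation 15 lists passed, 11 higher and 4 lower. The neuronal list had a median of -0.06, a mean of 0.06 and an upward test that did not pass (adjusted p = 0.972).

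Under DMSO, 8 genes differed between the classes in limma, 6 higher and 2 lower in the hypersensitive lines, and 9 (7 and 2) with the trend on the tested values. The histone genes HIST1H2AJ (12.88, 12.58 and 12.68 in A673, TC32 and TC252 against 7.53, 7.25 and 7.46 in EWS-502, ES-2 and TC71) and HIST1H2BM were higher in the hypersensitive lines by 5.30 (SE 0.16, adjusted p = 0.000299) and 4.74 (SE 0.33, adjusted p = 0.0197). So were the calcium binding protein gene S100A6 by 4.27 (SE 0.35), PHF11 by 3.81 (SE 0.29), the homeobox gene BARX2 by 3.79 (SE 0.32) and CAPG, an actin capping protein gene, by 3.27 (SE 0.27), with adjusted p of 0.0253 to 0.0261. KLHL4 differed by -4.01 (SE 0.38, adjusted p = 0.0459). HIST1H2AJ and HIST1H2BM are neighbours on chromosome 6, at 27814354 to 27814740 and 27815044 to 27815424, with close copies elsewhere, so their levels are uncertain. S100A6 lies on chromosome 1 from 153534599 to 153536244, PHF11 on chromosome 13 from 49495610 to 49528987, BARX2 on chromosome 11 from 129375940 to 129452279, CAPG on chromosome 2 from 85394748 to 85418432 and KLHL4 on the X chromosome from 87517749 to 87670050. At an unadjusted p under 0.05 there were 1380 genes, 778.2 expected by chance. Only HIST1H2AJ passed under every alternative run for it, since each of the other 7 genes lost its call when at least 1 line was left out.

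As lists under DMSO, genes activated by EWSR1-FLI1 (median 0.40), cholesterol synthesis (0.38), immediate early genes (0.28) and p53 targets (0.27) lay higher in the hypersensitive lines, and PERK and ATF4 targets (-0.63), ribosomal proteins (-0.21) and nuclear oxidative phosphorylation (-0.21) lower, with the preset correlation. With an estimated correlation 0 of these 7 passed (adjusted p = 0.713 for each). No member passed over all genes, and adjusted over the list alone the calls were 3 cholesterol genes higher and 1 lower, 2 immediate early genes, 1 gene activated by EWSR1-FLI1, 1 p53 target and 1 neuronal gene higher, and 1 heat shock gene lower. After quantile normalisation 5 lists passed as higher and 2 as lower. Without TC71, 3 lists passed. Medians and means differed in sign for the lists of LSD1 complexes, NRF2, metallothioneins, autophagy and histones, none of which passed.

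The size of the response, as the SD over genes of a line's mean difference, was 0.659 in A673, 0.714 in TC32, 0.503 in TC252, 0.649 in EWS-502, 0.377 in ES-2 and 0.782 in TC71. The SD between lines was 0.110 in the hypersensitive and 0.207 in the sensitive class (n = 3 lines each), and the class means differed by 0.0223, with an exact two-sided permutation p of 0.8, where 0.1 is the smallest that 3 against 3 lines allow. In the block of lower title numbers, with 2 hypersensitive lines and 1 sensitive line, the difference was 0.204, and in the other, with 1 and 2, it was -0.00178. Across genes, which are not independent replicates, responses of the 15 pairs of lines correlated by a mean of 0.627 ± 0.0953 (SD), with 0.692 within the hypersensitive class, 0.564 within the sensitive class and 0.626 between classes. No test was run on these means. TC32 and TC252 correlated most, at 0.835, but at 0.616 without TC252 replicate 3, when the highest other pair had 0.756.

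**Figure D4:**
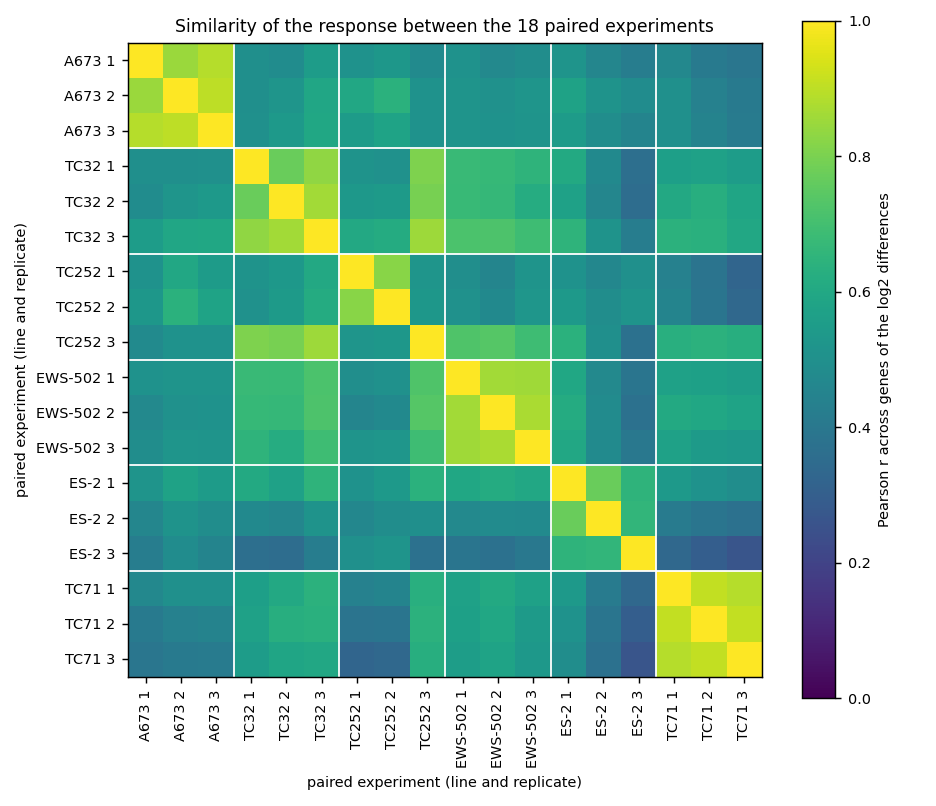
Pearson correlation across tested genes of the SP-2509 minus DMSO differences of 18 replicate pairs, with the pairs on both axes and r as a colour scale. TC252 replicate 3 correlated by 0.793 to 0.853 with TC32 pairs, 0.689 to 0.736 with EWS-502 pairs and 0.626 to 0.641 with TC71 pairs. It correlated by 0.521 and 0.531 with TC252 replicates 1 and 2. With A673 pairs r was 0.480 to 0.511 and with ES-2 pairs 0.372 to 0.638.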

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

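The tests of explanations below were chosen only after the results were seen, while the counts over other splits of the samples and the class tests were planned.

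HIF1A-AS2 rose further in the hypersensitive lines, with a class difference in response of 2.36, and LOC105370526 differed by 4.05. Reads of the overlapping HIF1A are argued against by its own class difference of -0.0223 (SE 0.266), and a change of the whole region by the median of 0.0112 (SD 0.510) over 7 tested genes within 1 Mb. That median left out the neighbour SNAPC1, at 1.81, and PRKCH has 1.30, neither of which passed, so the value bears on the region as a whole and a change of a few neighbouring genes stays open. Shrinkage of low values in the sensitive lines is argued against only narrowly, since HIF1A-AS2 was higher by 0.391 (SE 0.293) in the hypersensitive lines under DMSO, and 2 standard errors above that is just inside the bound of 1. A class-linked induction at this locus is therefore a hypothesis, and the call itself is lost with the trend on the tested values.

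TC252 replicate 3 responded most like TC32, but the likeness was not particular to that line. Its response also correlated with the EWS-502 pairs by 0.689 to 0.736 and with the TC71 pairs by 0.626 to 0.641. Both ranges lay above its 0.521 and 0.531 with TC252 replicates 1 and 2. With the A673 pairs it correlated by 0.480 to 0.511 and with the ES-2 pairs by 0.372 to 0.638. The values do not show whether replicate 3 or replicates 1 and 2 departed from the line's usual response. Its SP-2509 library differed from replicates 1 and 2 by 0.658 and 0.662 (root mean square), which differed from each other by 0.199, and its response correlated with the TC32 mean by 0.870. A TC32 library under a TC252 label is argued against by a median position of 1.06 (SD 0.206 over 29 genes that part the lines), on a scale with TC252 at 1 and TC32 at 0, and carry-over of TC32 RNA by an implied share of -1.52 percent (interquartile range 5.26, 27 genes) where the response would need 98.4 percent. A larger form of the response of replicates 1 and 2 is argued against by a correlation with their mean of 0.551, below the 0.823 of those replicates with each other. The design gives no biological group for a single replicate, so no biological explanation was tested, and a difference in exposure or culture stays open.

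TC32 DMSO replicate 2 held ES-2 transcripts at low level. All 16 genes private to ES-2 (100 percent) lay above both sibling libraries, with a median excess of 1.15, the highest of 120 combinations of library and line (second 0.766), and KRT8 stood at 7.46 against 5.91 and 5.72, with 11.89 in ES-2. Higher low values throughout the library are argued against by the highest median excess of genes private to another line, 0.113. Carry-over of ES-2 RNA, at an implied share of 3.53 percent, may be the source, and no biological explanation was tested. Private genes (a level of at least 7, a gap of 3 and at least 5 genes per line) were defined more loosely after the outcome of a stricter definition had been seen.

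HIST1H2AJ was tested as a class difference in response and gave -2.72. No explanation of it was tested. DDIT3 in TC71, at 1.23, and APELA in TC71, at -4.16, stood apart from the other 5 lines, 2 of 26 sets of 6 line values examined in this way (25 genes and the response size), where chance gives about 1 in 20 groups. By a test of the difference between lines, 11651 genes responded differently in the 6 lines. Of 146 named genes, 10 were called in opposite directions in at least 1 pair of lines, MROH2A, LCP1, CD68, UBE2C, CDT1, SLC7A5, MYC, CDC6, S100A6 and JAK1. LCP1, for example, stood at 2.04 in A673 and -0.48 in ES-2.

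For each line, 1 of the 10 splits of its 6 libraries called as many genes as the real one, the real one itself, and 10 splits are too few for a share under 0.05. The real counts were 8379 in A673, 9225 in EWS-502, 3823 in ES-2 and 10325 in TC71, with 0 as the highest other, 10127 in TC32 with 1688 and 7348 in TC252 with 6580. Among splits that part all 3 pairs, as the real one does, the highest others were 14 in TC32 and 477 in TC252. The counts of 6580 in TC252 and 1688 in TC32 come from splits that part only 1 pair. With the pair block, such a split estimates that pair's own difference between SP-2509 and DMSO. These counts are thus treatment contrasts of 1 pair and do not by themselves point to a structure other than treatment. Such splits gave 0 calls in A673, EWS-502, ES-2 and TC71. Why they gave more in TC252 and TC32 was not tested. In every line, the splits other than the real one also leave treatment effects in the residual spread. Their low counts were thus largely fixed in advance. For the mean response, 1 of 32 sign flips of whole lines gave as many as the 7111 genes called, and the highest other gave 0. No share smaller than 1 in 32 was possible. Flipping some of a set of lines with similar responses cancels their mean, so the low other counts show only that the lines share a direction. For the class comparisons, 10 splits of the 6 lines are too few for a share under 0.05: the response gave 3 genes with 0 as the highest other, and DMSO gave 8, with 2 splits as large, since the split with A673, ES-2 and TC71 together gave 14.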

How the results depend on the processing

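The trend on the tested values and the fits without TC252 replicate 3 or TC32 replicate 2 were chosen after the data were seen, and the rest was planned. No named gene, and no list in the mean response, reversed its direction while passing the threshold in either fit. Changes of sign between fits that both fell short of the threshold were not counted as reversals. Lists in the class comparisons were followed only as counts. The majority direction of calls turned with centring for the mean response and for 5 of the 6 lines. Of 118 named mean responses under 1298 alternatives, 1226 kept their side of the threshold, 58 lost it and 14 gained it, and all 144 alternatives of the 36 genes named by line kept it. Those 144 were quantile normalisation and leaving out each replicate. The fit on a line's own libraries alone was not run for these genes. Of 121 alternatives for 11 class differences in response, 17 lost the passing side of the threshold, as did 38 of 88 for 8 class differences under DMSO. For the 25 lists in the mean response, 23 of 275 lost it and 6 gained it. With a log2 difference of at least 1 required, which takes fewer genes by construction, calls numbered 1642 in A673, 2247 in TC32, 839 in TC252, 1785 in EWS-502, 332 in ES-2, 2843 in TC71 and 853 for the mean response. The treatment response in TC252 had 965 calls from its own libraries alone, whose spread holds replicate 3. Leaving out a replicate gave 939 to 3278 calls for the treatment response in ES-2, and the cause was not tested. With the spread between pairs in place of lines, 12528 genes were called for the mean treatment response over the 6 lines and 4517 for the class difference in treatment response. Without the replicate block these were 12535 and 4670. Both fits change the source of the spread and the number of values behind it at once, and these were not separated. The class difference under DMSO had 11756 calls with the spread between libraries. Fits on the spread between pairs or libraries take measurements of the same line as replicates. Sensitivity class is a property of the line, so these larger counts are no evidence for a statement over lines or classes. The fit without the block moved none of the 6 counts of calls within lines by over 1.5 times, and it was not run for lists. Without a filter on low values the class difference in response had 1 call, that under DMSO 26, and the similarity of responses was 0.501. With the trend on the tested values the class difference in response had 0 calls and the mean response 7358. Leaving out a replicate or line gave 1 to 3 calls for the class difference in response and 1 to 15 for that under DMSO. Lists passing in the mean response numbered 9 to 16, and under DMSO 3 to 9. With an estimated correlation 0 lists passed in each of the 3 comparisons. KDM1A passed after quantile normalisation, at -0.213. Where no cause is named for a change, the cause was not tested. Without TC252 replicate 3, 6288 genes were called for the mean response (6262 of them shared), 2 for the class difference in response, and 13 lists passed. Without TC32 replicate 2 these were 7054, 3 and 14. Without counts, what depth limits could not be examined.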

Other observations

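The families below were chosen after the values were seen, from 21 looked at, and the resemblance of lines was looked at in the same way.

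Values assigned to transfer RNA genes fell with SP-2509. Of 84 tested, 78 fell, 0 rose and 6 were not called. The median log2 was -1.22, and it was -1.16 after centring on library medians and -1.13 after quantile normalisation. The source of these reads (mature transfer RNA, precursors or overlapping transcripts) was not examined, so a fall of mature transfer RNA is not shown. By line the median ran from -0.50 in TC252 to -1.92 in TC71. Of 63 histone genes with the prefix HIST, 57 fell and 1 rose, with a median of -1.03. Members of both families share reads between near-identical copies. Of 17 tubulin genes, which encode the subunits of microtubules, 12 fell and 0 rose (median -0.68), and of 11 minichromosome maintenance genes 9 fell (-0.83).

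Of 14 genes for Kruppel-like transcription factors, 10 rose and 0 fell, with a median of 0.58. Of 27 SEC genes of vesicle transport, 16 rose and 2 fell (0.36), and of 164 ribosomal protein pseudogenes 56 rose and 2 fell (0.32). Each of these medians kept its sign under both scalings. Of 26 cytosolic ribosomal protein genes, 24 also rose, with a median of 0.34. Reads shared between these genes and the pseudogenes were not examined, so the pseudogenes may not be a separate observation. Under DMSO, TC32 and TC252 differed by an SD over genes of 0.440, against 0.818 to 1.05 for the other 14 pairs of lines.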
